A study of Mus musculus with 8 samples.

How the data were processed

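Gene expression was measured in neutrophils sorted by flow cytometry from mouse lung, with 1 array per sample, 8 arrays in all. The labels place 2 arrays in the naive group, 3 in the group infected with the nematode Nippostrongylus brasiliensis (called Nb here) and 3 in the group given bacterial lipopolysaccharide (LPS, 50 µg in 50 µl, into the airway). Treated and infected mice were sampled on day 2. Per the labels' protocols the RNA was amplified before it was labelled with Cy3. The design text speaks of independent replicates but does not name the animals behind them, so the p-values measure the spread between these samples. Per the file headers the arrays lie on 2 slides. Slide 1 holds naive 1, naive 2, Nb 1 and Nb 2, and slide 2 holds Nb 3 and the 3 LPS arrays, so naive and LPS share no slide.

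Each array has a scanner file of fluorescence intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Its processed intensity is background-subtracted and detrended within the array, per the file headers, and is not normalized between arrays. The same files give median spot and background intensity and yes-or-no quality calls for every spot. A separate deposited table of the authors holds log2 values, each centred on its feature's median over the 8 arrays. The submitters' processing notes name limma without a version. Checked against the scanner files, the log2 values of that deposited table match quantile-normalized median spot intensity to within 0.00394 on the log2 scale. It lists 21218 features, and the rule that chose them is not given in the sources used here.

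The files give no gene symbols. Symbols were taken by RefSeq accession from a table of the GRCm38.p6 assembly, used for names only. Of 55681 distinct probes, 26582 (47.7%) received 1 symbol, 29099 received none and 0 matched several. Among 26392 probes with a messenger RNA accession, 25869 received a symbol. Coordinates of unnamed regions are those of the array design, in build mm9.

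Processed intensity was divided by each array's 75th percentile over non-control spots. Values under the lowest scaled value of any spot well above background, 17.5 units, were set to that floor, and log2 was taken. Spots marked by the scanner software as outliers were left out. The spots of a probe were averaged. A probe was tested when it was well above background on at least 2 of the 8 arrays, which 29250 probes were. The probe with the highest mean stood for its gene, giving 13878 genes, of which 1100 lack a value on at least 1 array. A group with 1 value is tested with the spread of the others, which concerns 1 gene called between Nb and naive, 5 between LPS and naive and 1 between Nb and LPS. A fold change against a group with no array well above background is given as a lower bound, reckoned against the lowest signal called present on those arrays.

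The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with 1 coefficient per group and moderated errors (5 residual and 3.12 prior degrees of freedom). Contrasts were Nb minus naive, LPS minus naive and Nb minus LPS. Every test is two-sided. The p-values were adjusted by the Benjamini-Hochberg method, and a gene is called at an adjusted p under 0.05. Errors beside log2 fold changes are limma's standard errors. Errors beside levels are standard deviations, and levels are log2 relative to the array's 75th percentile. Figures were drawn with matplotlib 3.10.9.

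The comparisons, the alternatives, the 32 gene lists and the rule for naming genes were chosen before the data were examined. The named genes are, per comparison, the 10 genes higher and the 10 lower with the largest fold among called genes whose arrays do not overlap and that are well above background on every array of the brighter group. To these come up to 4 members of each gene list (the called ones with the largest change, or else the tested ones) and 19 genes fixed by name. One of those, Ly6g, has no probe that the accession table names, so it has no value. The fixed list of type 2 and alternative activation genes was drawn up with knowledge of the study's published account, so it is not independent evidence. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists of a comparison, and again with the correlation estimated from the data. These tests used only genes with a value on every array of the fit, while counts, medians and means cover all tested members. Camera thus used 24 of 32 interferon-stimulated genes, 32 of 37 TLR4 and NF-kappaB genes and 12 of 15 lung epithelial markers. In the Results each list's count is also given adjusted over the list alone.

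The gene and list tests were checked on data simulated with the real means and group sizes and with limma's moderated spreads. The noise was normal, no value was missing and no slide difference was put in, so rates on the real arrays may differ. For Nb against naive, 11.9% of 67 genes changed by 2-fold, 77.6% of 67 changed by 4-fold and 97.0% of 66 changed by 8-fold were called, with 9 false calls among 133. For LPS against naive the shares were 4.48%, 64.2% and 93.9%, with 4 false calls among 112. For Nb against LPS they were 13.4%, 82.1% and 95.5%, with 6 false calls among 133. In each comparison the 1 shifted list was called and 0 of the 31 others. The simulated genes varied independently of one another, so this check could not show how correlation between genes affects the list test.

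Alternatives were other normalizations and background corrections, the authors' own values, other filters and probe choices, slide as a fixed or a random block, each slide alone, a replicate block, 2 groups alone, array weights, a trended robust prior and each array left out in turn. A different floor, a different scaling set and each probe on its own were added after the data were seen. Naive lies only on slide 1 and LPS only on slide 2. For genes with a value on every array, the slide block therefore compares Nb 1 and Nb 2 with naive, and Nb 3 alone with LPS. For these comparisons it gives the estimates of slide 1 and slide 2 alone and is no separate check of them. The number of arrays limits the precision of every value.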

Results

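Messenger RNA levels were compared between lung neutrophils of naive mice (n = 2 arrays), of mice infected with Nippostrongylus brasiliensis (Nb, n = 3), a rodent nematode whose larvae pass through the lung, and of mice given LPS, a bacterial cell wall component, into the airway (n = 3). All mice were female BALB/c. Each array carried 62976 spots. Between 43.5% (LPS 1) and 50.5% (naive 1) of non-control spots were well above background, and 0 were saturated. The scanner software marked 3.66% of spots on LPS 1 as outliers, against 0.265% to 0.425% on the other arrays. Across genes, log2 signals of arrays of the same group correlated with r from 0.965 to 0.975, and those of different groups with r from 0.925 to 0.960. S100a8, a calcium-binding protein abundant in neutrophils, had a log2 level of 8.99 ± 0.10 (SD, n = 2) in naive, 8.77 ± 0.12 (n = 3) in Nb and 8.53 ± 0.20 (n = 3) in LPS. Csf3r, the receptor for granulocyte colony-stimulating factor, had levels of 9.24 ± 0.13 (n = 2), 8.99 ± 0.12 (n = 3) and 8.68 ± 0.09 (n = 2).

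**Figure D1:**
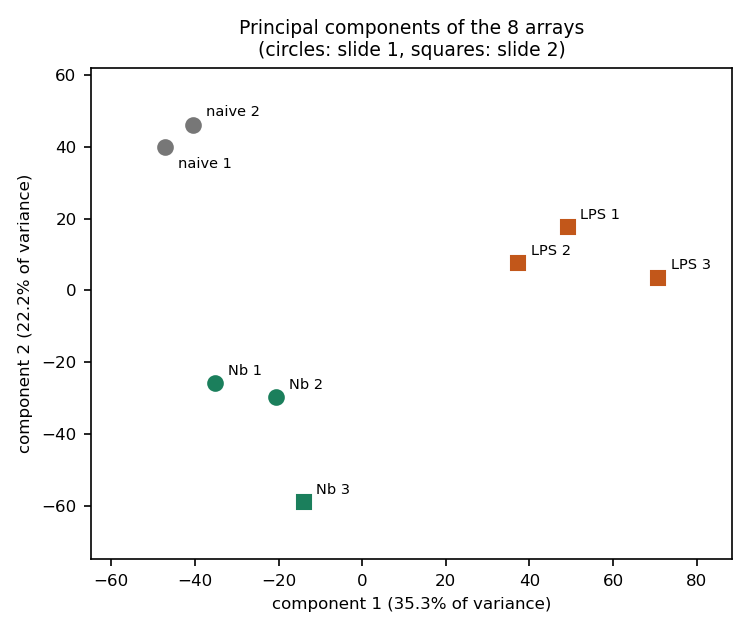
First and second principal components of the log2 levels of the genes tested, 1 point per array, with the share of the variance on each axis (35.3% and 22.2%); colours give the group and marker shapes the slide. The 3 groups lie apart, and Nb 3, on the slide of the LPS arrays, lies nearest the other Nb arrays.

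The comparison of Nb with naive asks how lung neutrophils differ during the worm's passage. Of 27 type 2 and alternative activation genes 6 were higher in Nb (adjusted p = 0.000293 for the list with camera; adjusted p = 0.0894 with an estimated correlation). Arg1, the arginase of alternatively activated cells, rose 41.5-fold (log2 fold change 5.38 ± 0.78, n = 3 against 2, adjusted p = 0.0239), and Retnla, a secreted resistin-like protein induced by type 2 cytokines, rose 21.0-fold (4.39 ± 0.86, adjusted p = 0.0484). Il13, the type 2 cytokine, rose 7.22-fold (2.85 ± 0.42, adjusted p = 0.0239), and Chil3, a chitinase-like protein, rose 4.26-fold (2.09 ± 0.39, adjusted p = 0.0497). Arg1 was above background on 1 of the 2 naive arrays, and its fold was 85.1 without naive 1 and 20.3 without naive 2. Some inflammatory genes rose too, though not as a list. Nos2, the inducible nitric oxide synthase, rose 21.9-fold (4.45 ± 0.36, adjusted p = 0.00464), Il23a, a subunit of interleukin 23, 13.8-fold (3.78 ± 0.30, adjusted p = 0.00883) and Tnf 7.74-fold (2.95 ± 0.32, adjusted p = 0.0124). With slide as a block the log2 fold changes were 5.25 for Arg1 (adjusted p = 0.0745), 3.89 for Retnla (0.138), 2.98 for Il13 (0.0683), 2.21 for Chil3 (0.119), 4.49 for Nos2 (0.0283), 3.78 for Il23a (0.0469) and 2.92 for Tnf (0.0533). Arg1 (highest adjusted p = 0.107) lost the call without naive 2, Nb 2 or Nb 3, Tnf (0.0693) without naive 2 or Nb 3 and Il13 (0.117) without naive 1, naive 2, Nb 1, Nb 2 or Nb 3. Retnla (0.205) lost the call without any one array but LPS 1 and Chil3 (0.167) without any one array.

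In all, 265 of 13878 genes passed the test, 171 higher and 94 lower in Nb. Those with the largest rise also included Ccl8, a chemokine (4.30 ± 0.47), Prok2, a secreted prokineticin (4.15 ± 0.32), and Rab15, a small GTPase of vesicle traffic (4.25 ± 0.33). Ggt1, which cleaves glutathione, was at least 18.9-fold higher, Mlc1 at least 15.2-fold and Stbd1 at least 14.8-fold. Among the genes that fell most, Rag1, a recombinase of antigen receptor genes, fell by 5.24 ± 0.49 on the log2 scale (adjusted p = 0.00883), Dntt, a polymerase of the same process, fell by 3.73 ± 0.43, Ly6d fell by 2.86 ± 0.33 and Myb, a transcription factor of blood precursors, fell by 2.76 ± 0.42. In Nb, Rag1 and Xkrx were above background on 1 of 3 arrays and Dntt and Abcg3 on 2. Fabp1, Abcg3 and Xkrx also fell, with log2 fold changes from -3.59 to -2.63. Fabp1 moved to -4.39 without naive 1 and -2.78 without naive 2 (adjusted p = 0.127), and Xkrx to -3.26 (0.0768) and -2.01 (0.210). Sprr1a was at least 14.1-fold lower, Tctex1d1 at least 7.37-fold and Resp18 at least 5.37-fold; without naive 1 these bounds were 6.45, 4.55 and 3.18, and without naive 2 they were 30.6, 11.9 and 9.09. Ccl8 (highest adjusted p = 0.0556) and Stbd1 (0.0792) lost their calls without naive 1, naive 2 or Nb 3, Mlc1 (0.0959) and Abcg3 (0.0930) without naive 1, naive 2 or Nb 2 and Dntt (0.0559) without naive 1 or Nb 3. Ly6d (0.0533), Sprr1a (0.0683) and Tctex1d1 (0.0654) lost their calls without Nb 2 or Nb 3, Myb (0.108) without naive 1, naive 2, Nb 2 or Nb 3 and Xkrx (0.210) without any one array. Fabp1 (0.127) lost the call without naive 2, Nb 1, Nb 2, Nb 3 or LPS 2 and Resp18 (0.0757) without Nb 1, Nb 2 or Nb 3.

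Of 27 measured type 2 and alternative activation genes, 6 rose, 0 fell and 21 were not called. Besides Arg1, Retnla, Il13 and Chil3 these were Chil4 (2.75 ± 0.44; 2.03 without naive 1 and 3.47 without naive 2) and Cish (1.45). Adjusted over the list alone 11 were called, 10 higher and 1 lower, on a list that is not independent evidence. Its median log2 fold change was 0.63 (camera adjusted p = 0.000293; adjusted p = 0.0894 with an estimated correlation). The median was 0.63 with slide as a block (adjusted p = 0.000166) and within slide 1 (4.38e-05), 0.40 (0.00304) without naive 1 and 0.95 (0.000203) without naive 2. Il33 (3.02 ± 0.75, adjusted p = 0.0868), Igf1 (2.13 ± 0.69, 0.154), Il4 (1.32 ± 0.73, 0.362) and Mrc1 (0.36 ± 0.46, 0.697) were not called. Among 25 chemokine ligand genes 4 rose (Ccl8, Ccl12, Ccl2 and Cxcl10), 1 fell (Ccl5) and 20 were not called; adjusted over the list alone 10 were higher and 1 lower. Ccl12 was at least 5.34-fold higher; Ccl2 had a log2 fold change of 1.99 ± 0.38 and Cxcl10 of 1.66 ± 0.29. The list rose with a median of 0.69 (adjusted p = 0.000178; adjusted p = 0.240 with an estimated correlation), and of 0.80 with slide as a block (4.73e-05) and within slide 1 (0.000137). Chil4 (highest adjusted p = 0.0959) lost the call without naive 1, Nb 1, Nb 2 or Nb 3, Cish (0.204) and Ccl2 (0.167) without any one array and Ccl8 (0.0556) without naive 1, naive 2 or Nb 3. Cxcl10 (0.154) lost the call without naive 1, naive 2, Nb 1, Nb 2, Nb 3 or LPS 1 and Ccl5 (0.178) without any one array but LPS 2.

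Of 15 specific and gelatinase granule genes, the proteins neutrophils store late in maturation, 4 rose (Chil3, which the type 2 list also holds, and 3 others), 0 fell and 11 were not called; 7 were higher adjusted over the list alone. Cd177, a neutrophil surface and granule protein, rose by 3.25 ± 0.46 on the log2 scale, Itgb2l by 2.10 ± 0.28 and Mmp8, a collagenase, by 1.45 ± 0.25. The list's median was 1.03 (adjusted p = 2.46e-06; adjusted p = 0.240 with an estimated correlation), and 1.01 with slide as a block (7.54e-06) and within slide 1 (1.21e-05). Of 28 matrix remodelling and growth factor genes 5 rose, 0 fell and 23 were not called; adjusted over the list alone 10 were higher and 2 lower. Timp1, an inhibitor of matrix proteases, rose by 2.91 ± 0.37 and Hbegf, an epidermal growth factor relative, by 2.33 ± 0.31. Mmp19 (1.67 ± 0.26) rose too. Tgm2, counted among the 5, has a value on only 1 naive array, and another of its probes gave -0.32. The list's median was 0.69 (adjusted p = 0.00575; adjusted p = 0.343 with an estimated correlation), 0.65 with slide as a block (0.00558) 0.65 within slide 1 (0.0208) and 0.45 (0.0378) without naive 2. Cell cycle genes rose as a list, with 1 of 30 called (Ccnb2, 1.67 ± 0.25), 5 higher adjusted over the list alone and a median of 0.98 (adjusted p = 2.39e-06; adjusted p = 0.279 with an estimated correlation). The slide block gave a median of 0.90 (2.71e-05), within slide 1 it was 0.90 (0.00015), and without naive 2 it was 0.50 (0.00222). Cd177 (highest adjusted p = 0.107), Itgb2l (0.0986), Timp1 (0.0775) and Hbegf (0.106) lost their calls without naive 1, naive 2, Nb 2 or Nb 3, Mmp8 (0.135) without naive 1, naive 2, Nb 1, Nb 2, Nb 3 or LPS 1 and Mmp19 (0.134) without naive 1, naive 2, Nb 1, Nb 2 or Nb 3. Tgm2 (0.0714) lost the call without Nb 2 or Nb 3 and Ccnb2 (0.116) without naive 1, naive 2, Nb 1 or Nb 3.

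Inflammatory and identity genes did not shift as lists. Of 37 TLR4 and NF-kappaB inflammatory genes, 5 rose (Nos2, Il23a, Tnf, Saa3 at 1.83 ± 0.35 and Il1a at 1.66), 0 fell and 32 were not called; adjusted over the list alone 7 were higher and 2 lower, and the median was 0.01 (adjusted p = 0.498). Il6 (0.95 ± 0.81), Il1b (-0.02 ± 0.23), Cxcl2 (-0.27 ± 0.21) and Cd14 (-0.02 ± 0.27) were not called. Of 32 interferon-stimulated genes 1 rose (Cxcl10), with 3 higher adjusted over the list alone, a median of -0.02, a mean of 0.04 and an upward camera direction (adjusted p = 0.970). Of 28 neutrophil identity genes 2 rose (Cd177 and Mmp8) and 26 were not called, with 4 higher adjusted over the list alone. Their median was -0.05, their mean 0.23 and the camera direction upward (adjusted p = 0.592). S100a9 (-0.71 ± 0.40, adjusted p = 0.362) and Cxcr2 (-0.15 ± 0.30, 0.805) were not called. Saa3 (highest adjusted p = 0.165) lost the call without any one array but naive 1 and Il1a (0.193) without any one array.

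Of 16 T cell markers 0 rose, 1 fell (Cd2, -1.58 ± 0.28) and 15 were not called, with 12 lower adjusted over the list alone; the median was -1.12 (adjusted p = 4.77e-07; adjusted p = 0.240 with an estimated correlation), and -1.06 with slide as a block (5.36e-07) and within slide 1 (4.84e-07). B cell markers had 4 of 10 lower (among them Cd79b, Fcrla and Blnk, from -1.83 to -1.37), 8 lower adjusted over the list alone and a median of -1.37 (adjusted p = 2.39e-06; adjusted p = 0.0681 with an estimated correlation), -1.41 with slide as a block (5.66e-06) and within slide 1 (9.07e-06). NK cell markers had 3 of 11 lower, among them Klra8 (-1.99 ± 0.24), Gzma (-1.93 ± 0.29) and Klra4, which was at least 3.72-fold lower; 8 were lower adjusted over the list alone. Their median was -1.48 (adjusted p = 3.55e-06; adjusted p = 0.0681 with an estimated correlation), -1.39 with slide as a block (5.55e-05) and within slide 1 (4.44e-05). Genes of antigen presentation by MHC class II had 0 of 12 called, 3 lower adjusted over the list alone and a median of -0.48 (adjusted p = 0.00575; adjusted p = 0.240 with an estimated correlation), -0.52 with slide as a block (0.00885) and within slide 1 (0.00463). Red cell markers had 1 of 5 lower (Slc4a1, -2.10 ± 0.41), 2 adjusted over the list alone and a median of -0.62 (adjusted p = 0.0119; adjusted p = 0.279 with an estimated correlation), -0.82 with slide as a block (0.00534) and within slide 1 (0.0127), and -0.37 (0.0435) without Nb 2. Cd2 (highest adjusted p = 0.198) lost the call without any one array, Cd79b (0.112) and Blnk (0.121) without naive 1, naive 2, Nb 1, Nb 2 or Nb 3 and Fcrla (0.127) without naive 1, naive 2, Nb 2 or Nb 3. Klra8 (0.0935) lost the call without naive 2, Nb 2 or Nb 3, Gzma (0.116) without naive 2, Nb 1, Nb 2 or Nb 3 and Klra4 (0.178) without naive 1, naive 2, Nb 1, Nb 2, Nb 3 or LPS 3. Slc4a1 (0.218) lost the call without any one array but Nb 1.

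Lung epithelial markers lay the other way, with 0 of 15 called, 7 higher adjusted over the list alone and a median of 1.34 (adjusted p = 0.0224; adjusted p = 0.352 with an estimated correlation). The median was 1.15 with slide as a block (0.0490) and within slide 1 (0.00415), and 1.01 (0.187) without naive 2 and 1.37 (0.0553) without Nb 1. The surfactant genes Sftpd (3.20 ± 0.70, adjusted p = 0.0868), Sftpa1 (3.02 ± 0.63, 0.0595) and Sftpb (2.95 ± 0.76, 0.0951) were not called, Sftpd with values on 2 Nb arrays. Endothelial and fibroblast markers had 0 of 13 called, 3 higher adjusted over the list alone and a median of 0.75 (adjusted p = 0.0437; adjusted p = 0.600 with an estimated correlation). It was 0.45 with slide as a block (0.111) and within slide 1 (0.0218), and the call ended without naive 1 (median 0.32, adjusted p = 0.498), Nb 1 (0.66, 0.0681) or Nb 3 (0.45, 0.112); without naive 2 the median was 1.38 (0.0037). Ribosomal protein genes had 0 of 44 called, 0 adjusted over the list alone and a median of -0.26 (adjusted p = 0.00780; adjusted p = 0.600 with an estimated correlation), -0.30 with slide as a block (0.00303) and within slide 1 (0.00169), and -0.14 (0.120) without naive 2. Macrophage and dendritic cell markers had 1 of 25 higher (Car4, 2.10 ± 0.37), 2 higher and 3 lower adjusted over the list alone, a median of 0.04, a mean of 0.08 and a downward camera direction (adjusted p = 0.985). Car4 (highest adjusted p = 0.154) lost the call without any one array.

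The count fell to 17 genes with slide as a block, to 17 without Nb 3, 30 without Nb 2, 34 without naive 2, 66 without naive 1, 115 without Nb 1 and 172 without LPS 1. The slide block gives Nb 3 no weight in this comparison, so its count and that without Nb 3 come from nearly the same fit. The list medians with slide as a block and within slide 1 likewise rest on the same arrays and are not separate checks. Within slide 1 limma called 0 genes, with 2274 at an unadjusted p under 0.05 against 2697 for all arrays.

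**Figure D2:**
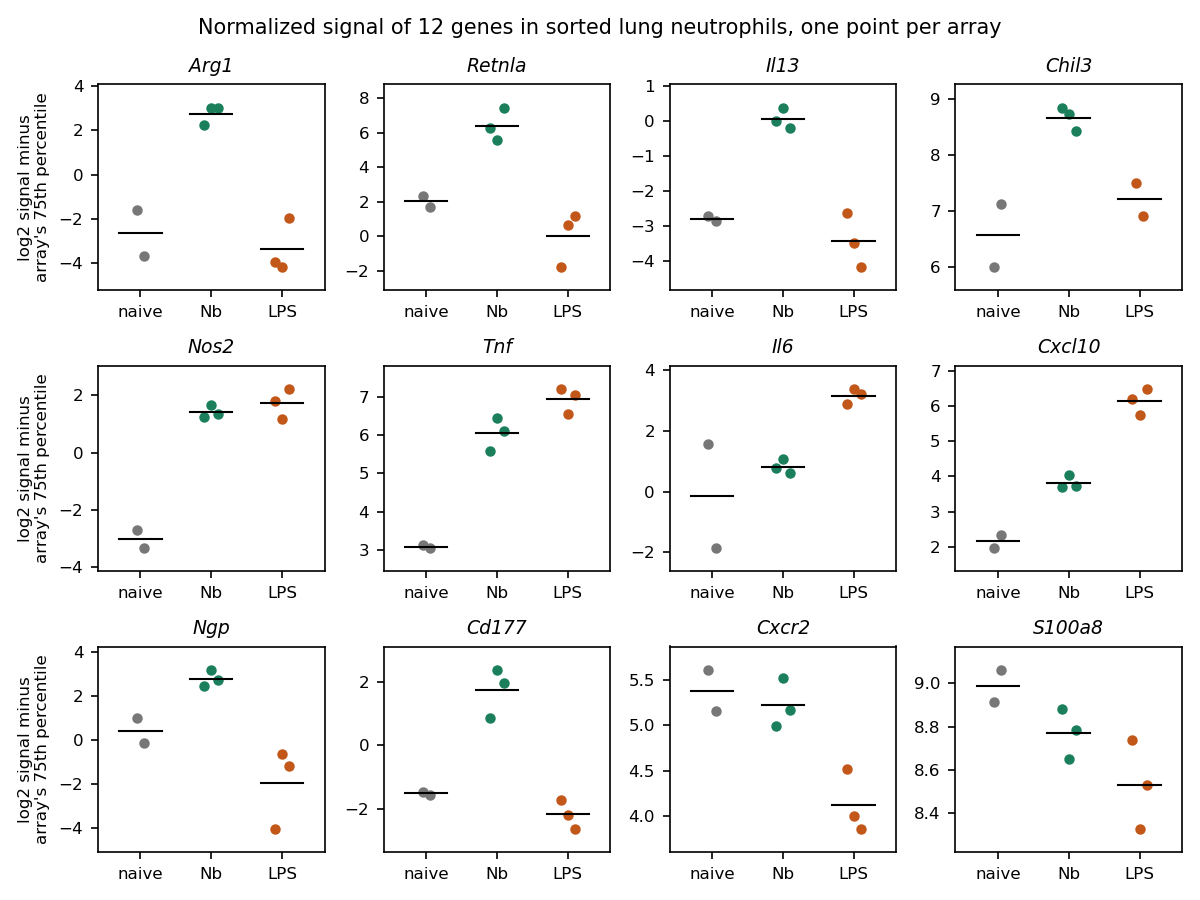
Log2 levels of 12 genes relative to each array's 75th percentile, 1 point per array and group means as bars. Arg1, Retnla and Il13 are highest in Nb, Cxcl10 is highest in LPS, and S100a8 lies between 8.33 and 9.06 on all arrays.

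The comparison of LPS with naive describes the response to a bacterial stimulus. On arrays that share no slide with naive, 13 of 37 TLR4 and NF-kappaB inflammatory genes and 15 of 32 interferon-stimulated genes were higher in LPS. As lists both had an adjusted p = 0.626 with an estimated correlation, against 0.000301 and 8.29e-05 with camera's preset one. Nos2 rose 26.8-fold (log2 fold change 4.74 ± 0.36, n = 3 against 2, adjusted p = 0.001), Cxcl10, a chemokine induced by interferons, 15.7-fold (3.97 ± 0.29, adjusted p = 0.001), Tnf 14.3-fold (3.84 ± 0.32, adjusted p = 0.00138) and Il6 9.84-fold (3.30 ± 0.81, adjusted p = 0.0407). The 2 naive arrays differed in Il6, whose fold was 32.1 without naive 1 and 3.02 without naive 2 (adjusted p = 0.0651). Cxcr2, the receptor that guides neutrophils to chemokines, fell by 1.25 ± 0.30 on the log2 scale (adjusted p = 0.0372). With slide as a block these log2 fold changes were 4.84 (adjusted p = 0.0628) for Nos2, 4.12 (0.0550) for Cxcl10, 3.76 (0.0845) for Tnf, 3.61 (0.378) for Il6 and -1.17 (0.441) for Cxcr2. No slide holds both groups, so no value within a slide exists. Il6 (highest adjusted p = 0.102) lost the call without any one array but naive 1 and Cxcr2 (0.190) without any one array but LPS 1.

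In all, 1460 of 13878 genes passed, 921 higher and 539 lower in LPS. The largest rises were in Plekhg4 (6.87 ± 0.51; 6.27 without naive 1 and 7.46 without naive 2), Rab15 (6.71 ± 0.33), Txlnb (5.20 ± 0.70), Neil2, a DNA repair glycosylase (4.77 ± 0.44), Mtmr7 (4.67 ± 0.29) and Car13, a carbonic anhydrase (4.66 ± 0.51). Adgrf3 was at least 41.5-fold higher, Syngr1 at least 36.7-fold and Htr2b, a serotonin receptor, at least 29.5-fold. Rag1 was at least 31.8-fold lower, Dpf1 at least 52.9-fold, Sprr1a at least 10.6-fold and Nkain4 at least 8.17-fold. Without naive 1 the bounds of Dpf1, Sprr1a and Nkain4 were 20.4, 4.86 and 3.44; without naive 2 they were 137, 23.1 and 19.4. Dntt fell by 3.53 ± 0.43, and Rbp3, Olfr76, Dlx5, Klhl29 and Nhlh1 fell with log2 fold changes from -4.47 to -3.39 but each lost its call without naive 1 (adjusted p from 0.106 to 0.200), naive 2 (0.0738 to 0.149) or LPS 3 (0.0589 to 0.112, Olfr76 then at -3.60). The calls of Nhlh1, Dlx5 and Rbp3 also ended without LPS 1, those of Nhlh1 and Rbp3 without LPS 2 and that of Rbp3 without Nb 2. In the slide block fit the 5 ran from -2.02 (Olfr76, adjusted p = 0.517) to -0.38 (Rbp3, 0.915). Plekhg4 was above background on 1 naive array, Klhl29 and Dlx5 on 1 LPS array and Olfr76, Rbp3 and Slc4a1 on 2. Gbp5, Usp18, Irgm1, Il23a, Mtmr7, Krt18, Cd3d, Lrg1, Chil3 and Csf3r have values on 2 LPS arrays. Retnla (-2.00 ± 0.86, adjusted p = 0.162), Arg1 (-0.71 ± 0.78, 0.576), Il13 (-0.63 ± 0.42, 0.352) and Chil3 (0.64 ± 0.42, 0.353) were not called. Il4, Il33, Igf1, Mrc1, Il1b, Cxcl2, Cd14, S100a8, S100a9 and Csf3r were not called either, with log2 fold changes from -0.73 to 0.77. Nkain4 (highest adjusted p = 0.148) lost the call without naive 1, LPS 1 or LPS 3.

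Interferon-stimulated genes had 15 of 32 higher, 0 lower and 17 not called, and adjusted over the list alone 20 higher and 1 lower. Gbp5 (3.78 ± 0.31), Usp18 (2.47 ± 0.30) and Irgm1 (2.30 ± 0.30) rose beside Cxcl10. Gbp5, Usp18 and Irgm1 each lack a value on 1 LPS array, so camera left them out. The list's median over all members was 1.06 (camera adjusted p = 8.29e-05, and 0.626 with an estimated correlation), and 1.11 with slide as a block (9.16e-05). TLR4 and NF-kappaB inflammatory genes had 13 of 37 higher, 0 lower and 24 not called, and adjusted over the list alone 18 higher and 1 lower. Besides Nos2, Tnf and Il6 these included Il23a (4.10 ± 0.33). The list's median was 0.69 (adjusted p = 0.000301; adjusted p = 0.626 with an estimated correlation), and 0.89 with slide as a block (4.99e-07). Of 25 chemokine ligands 7 rose, among them Ccl2 (3.01 ± 0.38), Cxcl16 (2.87 ± 0.33) and Cxcl1 (2.02 ± 0.26), and 18 were not called; 10 were higher adjusted over the list alone. The list's median was 1.02 (adjusted p = 0.0446; adjusted p = 0.626 with an estimated correlation) and 1.11 with slide as a block (0.0163), and its call ended without naive 1 (median 0.54, adjusted p = 0.0891), Nb 3 (1.02, 0.0621) or LPS 2 (1.04, 0.0758); without LPS 3 the median was 0.39 (0.0397). Cell cycle genes had 1 of 30 higher (Mki67, 3.46 ± 0.33), 1 adjusted over the list alone and a median of 0.62 (adjusted p = 0.00929; adjusted p = 0.626 with an estimated correlation). The slide block gave 0.15 (0.574); the median was 0.15 without naive 2 (0.379) and 0.49 without LPS 2 (0.0758). Irgm1 (highest adjusted p = 0.0520) lost the call without naive 1.

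Neutrophil identity genes had 1 of 28 higher (Cxcr1, 1.18 ± 0.31), 5 lower and 22 not called, and adjusted over the list alone 2 higher and 8 lower. Trem1, an activating receptor, fell by 2.25 ± 0.46, Lrg1 fell by 1.34 ± 0.32 and Mmp8 fell by 1.03 ± 0.25. The median was -0.54 (adjusted p = 0.00929; adjusted p = 0.626 with an estimated correlation), and -0.48 with slide as a block (0.171). Specific and gelatinase granule genes had 1 of 15 lower (Mmp8), 1 higher and 3 lower adjusted over the list alone, and a median of -0.29 (adjusted p = 0.368). Type 2 and alternative activation genes had 3 of 27 higher (Areg at 2.41 ± 0.37, Socs1 at 2.24 ± 0.25 and Cish at 1.51 ± 0.28), 4 adjusted over the list alone, and a median of 0.10 (adjusted p = 0.536). Matrix remodelling genes had 5 of 28 higher, 2 lower and a median of 0.14 (adjusted p = 0.536); adjusted over the list alone 7 were higher and 4 lower. Mmp14, a membrane protease, was at least 7.79-fold higher, and Plau had a log2 fold change of 2.31 ± 0.39. Cxcr1 (highest adjusted p = 0.251) lost the call without any one array but LPS 2, Lrg1 (0.189) without any one array and Mmp8 (0.154) without any one array but LPS 3. Trem1 (0.129) lost the call without naive 1, naive 2 or LPS 3, Areg (0.0685) and Plau (0.0803) without naive 2 and Cish (0.110) without naive 1 or LPS 3. Mmp14 (0.0520) lost the call without naive 1.

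T cell markers had 2 of 16 lower (Cd3d, -1.53 ± 0.25, and Tcf7, -1.33 ± 0.30), 7 adjusted over the list alone and a median of -0.80 (adjusted p = 0.000984; adjusted p = 0.626 with an estimated correlation), -0.64 with slide as a block (0.101). B cell markers had 2 of 10 lower (Cd22, -1.71 ± 0.42, and Cd79b, -1.56 ± 0.28), 5 adjusted over the list alone and a median of -0.84 (adjusted p = 0.0167; adjusted p = 0.555 with an estimated correlation), -0.83 with slide as a block (0.124). NK cell markers had 1 of 11 lower (Gzma, -1.13 ± 0.29; -0.72 without naive 2), 3 adjusted over the list alone and a median of -0.54 (adjusted p = 0.0167; adjusted p = 0.555 with an estimated correlation), -0.48 with slide as a block (0.401). Red cell markers had 1 of 5 lower (Slc4a1, -2.32 ± 0.41), 3 adjusted over the list alone and a median of -0.76 (adjusted p = 0.0185; adjusted p = 0.626 with an estimated correlation), -1.09 with slide as a block (0.0176), and their call ended without naive 2 (0.0501) or LPS 2 (0.0584). Lung epithelial markers had 2 of 15 higher (Krt18, 3.20 ± 0.38, and Lamp3, 1.29 ± 0.29), 2 adjusted over the list alone, a median of 0.06, a mean of 0.30 and a downward camera direction (adjusted p = 0.880). Camera left out Krt18, which lacks a value on 1 LPS array. Macrophage and dendritic cell markers had 3 of 25 higher and 3 adjusted over the list alone. These were Ctsk (1.77 ± 0.42, adjusted p = 0.0370), Adgre1 (1.49 ± 0.27, 0.0182) and Car4 (1.49 ± 0.37, 0.0414). The list's median was 0.11 (camera adjusted p = 0.589). Adgre1 was lower in Nb than in LPS (-1.45 ± 0.25, 0.0146). Whether other cell types add to the LPS changes was not tested. Cd3d (highest adjusted p = 0.0848) and Slc4a1 (0.0926) lost their calls without naive 1, naive 2 or LPS 3, Tcf7 (0.169) without naive 1, naive 2, Nb 2, LPS 1 or LPS 3 and Cd22 (0.157) without naive 1, naive 2, Nb 2, LPS 2 or LPS 3. Cd79b (0.106) lost the call without naive 1 or LPS 3, Gzma (0.228) without any one array and Lamp3 (0.159) without naive 1, naive 2, LPS 1 or LPS 3.

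The count was 8 genes with slide as a block (1684 at an unadjusted p under 0.05), 265 without naive 1, 341 without naive 2, 477 without LPS 3 and 953 without Nb 2. Batch and group cannot be told apart here beyond what the Nb arrays on both slides tell.

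The comparison of Nb with LPS sets the neutrophils of worm infection against those of a bacterial stimulus. Retnla was 84.2-fold higher in Nb (log2 fold change 6.40 ± 0.77, n = 3 against 3, adjusted p = 0.00427), Arg1 67.7-fold (6.08 ± 0.69, adjusted p = 0.00349) and Il13 11.2-fold (3.48 ± 0.38, adjusted p = 0.00303). The granule genes Ngp (26.8-fold, 4.74 ± 0.81, adjusted p = 0.0152) and Cd177 (15.1-fold, 3.91 ± 0.41, adjusted p = 0.00253) were higher in Nb as well. Of 32 interferon-stimulated genes 16 were lower in Nb, among them Cxcl10 (-2.32 ± 0.26, adjusted p = 0.00319); the list had an adjusted p = 0.371 with an estimated correlation. With slide as a block Nb 3 alone stands against the LPS arrays. The log2 fold changes were then 7.40 for Retnla, 6.34 for Arg1, 3.22 for Il13, 4.69 for Ngp, 4.15 for Cd177 and -2.41 for Cxcl10. In LPS, Arg1 and Il13 were above background on 1 of 3 arrays and Ngp on 2. Without LPS 1 Retnla was at 5.50 and Ngp at 3.70; Ngp was at 5.41 without LPS 2, and Arg1 at 6.78 without LPS 3. Nos2 (-0.29 ± 0.32, adjusted p = 0.590), Tnf (-0.89 ± 0.28, 0.0911), Il6 (-2.35 ± 0.73, 0.0846) and Chil3 (1.45 ± 0.39, 0.0630) were not called. Ngp (highest adjusted p = 0.0537) lost the call without Nb 2.

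In all, 1191 of 13878 genes passed, 457 higher and 734 lower in Nb. Ccl8 (4.85 ± 0.42), Vax2, a homeobox factor (5.54 ± 1.23), and Actg2, a smooth muscle actin (4.64 ± 1.10), were among the highest. Ccl8 and Actg2 were above background on 1 LPS array and Igf1 on 2. Actg2 was at 6.10 without Nb 1, 3.96 without Nb 2 (adjusted p = 0.115) and 3.85 without Nb 3 (0.104). Actc1, an actin of heart muscle, was at least 37.8-fold higher (79.6 without Nb 1, 22.4 without Nb 3) and Col18a1, a basement membrane collagen, at least 10.6-fold. Vax2, Gbp5, Usp18, Ccl3, Lrg1, Sftpc, Cldn5, Mtmr7, Chil3 and Csf3r have values on 2 LPS arrays. Igf1, a growth factor, was higher in Nb than in LPS by 2.55 ± 0.62 (adjusted p = 0.0419, and 3.32 without LPS 3). Cxcr2 was higher by 1.10 ± 0.27 (0.0421), with mean levels of 5.38 in naive, 5.23 in Nb and 4.13 in LPS. The lower end held Plekhg4 (-5.14 ± 0.46), Il1f6, an interleukin 36 (-4.60 ± 0.38), Atp8b5 (-4.33 ± 0.53), Plcxd2 (-4.28 ± 0.22) and Txlnb (-4.25 ± 0.63). Slc26a11, Ceacam18, Htr2b and Mtmr7 were lower in Nb than in LPS, with log2 fold changes from -3.92 to -3.71. Kctd19 was at least 12.6-fold lower. Slc26a11 had mean levels of 2.52 in naive, 2.52 in Nb and 6.43 in LPS. Without Nb 1 Atp8b5 was at -4.96 and Htr2b at -4.35, and without Nb 2 Txlnb was at -4.98 and Htr2b at -3.15. Htr2b, Ceacam18 and Txlnb were above background on 2 of 3 Nb arrays. Il33, Il4, Mrc1, Il1b, Cxcl2, Cd14, S100a8, S100a9 and Csf3r were not called, with log2 fold changes from -0.51 to 2.24. Vax2 (highest adjusted p = 0.168) lost the call without Nb 1, Nb 2, Nb 3, LPS 1, LPS 2 or LPS 3, Actg2 (0.115) without any one array but Nb 1 and Igf1 (0.112) without any one array but LPS 3. Cxcr2 (0.125) lost the call without any one array but LPS 1 and Ceacam18 (0.0629) without Nb 2, Nb 3 or LPS 3.

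Of 32 interferon-stimulated genes 0 were higher in Nb, 16 lower and 16 not called, and adjusted over the list alone 1 was higher and 20 lower. Gbp5 (-2.53 ± 0.28), Usp18 (-2.51 ± 0.27) and Ifit2 (-2.50 ± 0.26) had the largest changes. Camera left out Gbp5 and Usp18. The list's median was -1.11 (camera adjusted p = 2.18e-06, and 0.371 with an estimated correlation). It was -1.16 with slide as a block and within slide 2, which here are the same contrast of Nb 3 alone with LPS. For every list of this comparison, values with slide as a block and within slide 2 rest on that single Nb array and are not separate checks. Of 37 TLR4 and NF-kappaB genes 10 were lower, 0 higher and 27 not called, with 13 lower adjusted over the list alone. Irak3 (-1.57 ± 0.24), Traf1 (-1.55 ± 0.21), Ccl3 (-1.33 ± 0.21) and Cxcl1 (-1.33 ± 0.24) were among them. Their median was -0.50 (adjusted p = 6.75e-05; adjusted p = 0.458 with an estimated correlation), and -0.70 with slide as a block (7.66e-06) and within slide 2 (1.31e-05). Chemokine ligands parted, with 2 of 25 higher (Ccl8 and Ccl12), 7 lower (such as Cxcl16, -2.11 ± 0.29) and 16 not called; adjusted over the list alone 6 were higher and 9 lower, and the median was 0.17 (adjusted p = 0.995). Ccl12 was at least 4.09-fold higher. Ccl3 (highest adjusted p = 0.0638) lost the call without Nb 1, Nb 2 or LPS 3 and Cxcl1 (0.0548) without Nb 1, Nb 3 or LPS 3.

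Specific and gelatinase granule genes had 6 of 15 higher in Nb, 0 lower and 9 not called, and adjusted over the list alone 10 higher and 1 lower. Itgb2l (2.78 ± 0.25) and Mmp8 (2.48 ± 0.22) were higher in Nb than in LPS beside Ngp and Cd177. The median was 0.89 (adjusted p = 2.18e-06; adjusted p = 0.334 with an estimated correlation), and 0.94 with slide as a block (7.66e-06) and within slide 2 (4.92e-05). Of 28 neutrophil identity genes 7 were higher, among them Lrg1 (2.77 ± 0.29) and Trem1 (1.82 ± 0.41), 0 lower and 21 not called; 8 were higher adjusted over the list alone. The median was 0.41 (adjusted p = 0.000502; adjusted p = 0.458 with an estimated correlation), and 0.37 with slide as a block (0.0157) and within slide 2 (0.0193). Cholesterol synthesis genes had 3 of 18 higher (among them Stard4 at 1.42 ± 0.27 and Fdps at 1.42 ± 0.21) and 9 higher adjusted over the list alone. Their median was 0.67 (adjusted p = 0.00122; adjusted p = 0.324 with an estimated correlation), and 0.76 with slide as a block (0.00636) and within slide 2 (0.0115). Type 2 and alternative activation genes had 5 of 27 higher (Retnla, Arg1, Il13, Chil4 at 2.56 ± 0.39 and Igf1) and 2 lower (Socs1 and Pdcd1lg2). Adjusted over the list alone 8 were higher and 3 lower, which is not independent evidence. The list's median was 0.39 (adjusted p = 0.0862), 0.52 with slide as a block (0.0822) and within slide 2 (0.139), and without LPS 3 the list was called (0.0400). Matrix remodelling genes had 4 of 28 higher, led by Timp1 (2.61 ± 0.33), 3 lower, led by Inhba (-2.21 ± 0.38), 5 higher and 5 lower adjusted over the list alone, and a median of 0.28 (adjusted p = 0.222). Heat shock genes had 1 of 15 higher (Hspb1, 1.37 ± 0.25), 1 adjusted over the list alone and a median of 0.25 (adjusted p = 0.0340; adjusted p = 0.334 with an estimated correlation). The median was 0.37 with slide as a block (0.0197) and 0.39 within slide 2 (0.0190), and the call ended without Nb 3 (median 0.14, adjusted p = 0.104), LPS 1 (0.27, 0.0576) or LPS 2 (0.10, 0.0669). Trem1 (highest adjusted p = 0.0905) lost the call without naive 1, naive 2, Nb 1, Nb 2, LPS 1 or LPS 3, Stard4 (0.0647) without Nb 1, Nb 2, Nb 3 or LPS 3 and Inhba (0.0543) without Nb 2. Hspb1 (0.0605) lost the call without Nb 1, Nb 2, Nb 3 or LPS 1 and Pdcd1lg2 (0.0654) without Nb 1, Nb 2, Nb 3, LPS 1 or LPS 3.

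Lung epithelial markers had 1 of 15 higher in Nb (Sftpc, 2.71 ± 0.61; 2.06 without LPS 2 and 3.36 without LPS 3), 4 higher and 1 lower adjusted over the list alone, and a median of 1.07 (adjusted p = 0.0120; adjusted p = 0.371 with an estimated correlation). It was 1.71 with slide as a block (0.00617), 1.67 within slide 2 (0.0117), 1.73 (0.0032) without LPS 2 and 0.86 (0.0545) without LPS 3. Endothelial and fibroblast markers had 2 of 13 higher (Lyve1, 1.62 ± 0.41, and Cldn5, 1.33 ± 0.31), 3 adjusted over the list alone and a median of 1.04 (adjusted p = 0.00782; adjusted p = 0.515 with an estimated correlation), 1.60 with slide as a block (0.00153) and within slide 2 (0.00704). NK cell markers had 1 of 11 lower (Klra8, -1.45 ± 0.22), 1 adjusted over the list alone and a median of -0.66 (adjusted p = 0.0340; adjusted p = 0.334 with an estimated correlation), -0.67 with slide as a block (0.00920) and within slide 2 (0.0105), and -0.59 (0.165) without Nb 3. Basophil and mast cell markers were not called (1 of 5 higher, Gata2 at 2.77 ± 0.30; 1 adjusted over the list alone; median 0.72, adjusted p = 0.0505, and 0.00525 with the fry test), and their median was 0.75 with slide as a block (0.152) and within slide 2 (0.0952). Monocyte markers had 3 of 11 higher (Vcan at 1.57 ± 0.32, F13a1 at 1.25 ± 0.23 and Ly6c1 at 1.18 ± 0.20), 3 adjusted over the list alone and a median of 0.03 (adjusted p = 0.278), -0.02 with slide as a block (0.244). Sftpc (highest adjusted p = 0.139) lost the call without Nb 1, Nb 2, Nb 3, LPS 1, LPS 2 or LPS 3, Lyve1 (0.132) without any one array but LPS 3 and Cldn5 (0.133) without any one array. Vcan (0.0747) lost the call without Nb 2, Nb 3, LPS 1 or LPS 3, F13a1 (0.0638) without Nb 2, Nb 3 or LPS 3 and Ly6c1 (0.0543) without Nb 2.

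**Figure D3:**
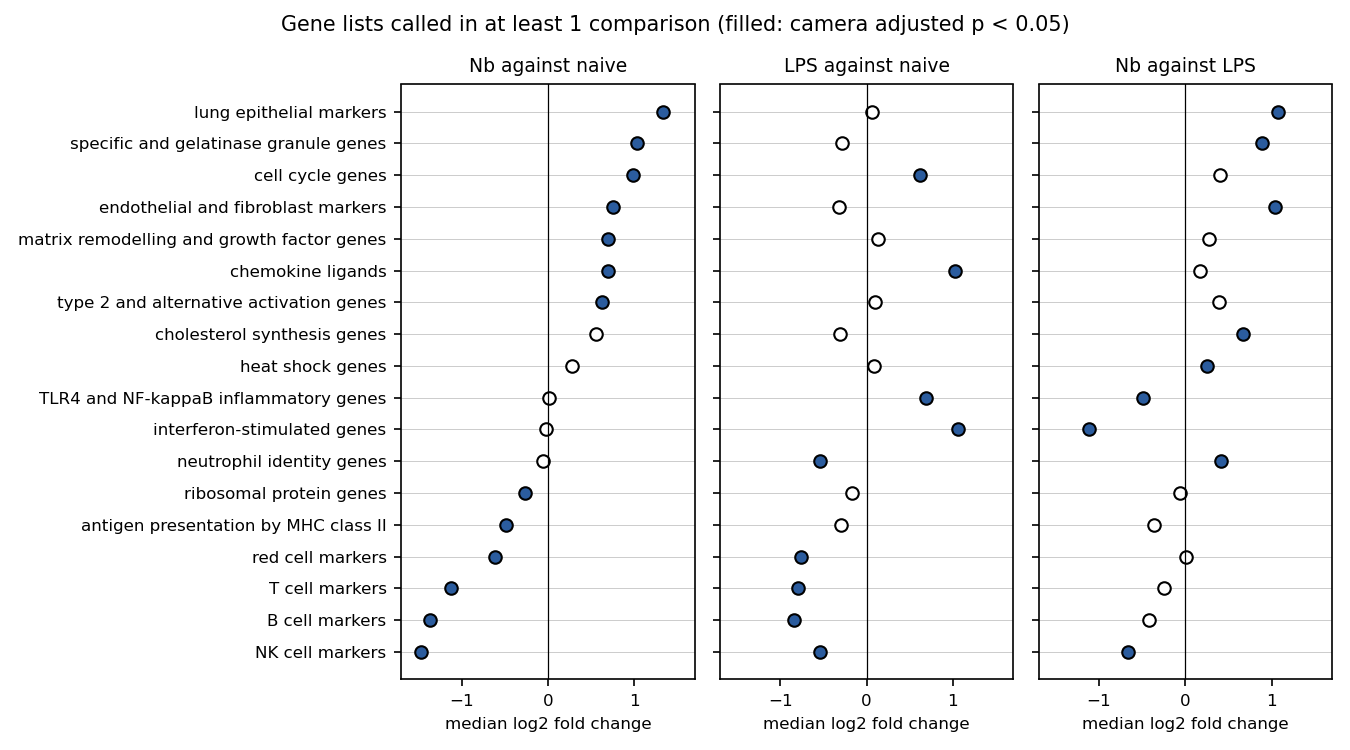
Median log2 fold change of the 18 gene lists that camera called in at least 1 comparison, 1 panel per comparison; filled points are called at an adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes lie at 1.06 in LPS against naive and at -1.11 in Nb against LPS.

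The count was 193 genes with slide as a block, 442 without Nb 1, 444 without Nb 2, 459 without LPS 3, 532 without Nb 3 and 689 without LPS 1. Within slide 2, which holds a single Nb array, limma called 0 genes, with 2089 at an unadjusted p under 0.05 against 3712 for all arrays.

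Some genes were called against naive in both Nb and LPS. In the same direction, 77 were higher and 59 lower in both, among them Nos2, Tnf, Il23a, Rab15, Rag1 and Dntt, and 2 genes were called in opposite directions. Independent lists of these sizes would share 11.3 and 3.65 genes. Both comparisons use the same 2 naive arrays. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.557, which lies below the mean of 0.600 in 100 simulations of unchanged groups that share the naive arrays. Their covariance was 0.380, against 0.109 simulated, a difference of 0.271. The naive arrays are too few to split, so part of the excess overlap may come from the shared controls. With slide as a block, 3 genes were called in both.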

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

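Every test in this part was laid down before its result was seen, except the values of Vpreb1, Vpreb3, Car4, Ctsk, Itgax and Siglecf and the choice of 4 precursor genes and of regions, which were made afterwards. Probes without a gene symbol take no part in the comparisons above, yet some of them differed between groups. Of 11767 such probes tested with limma, 33 were called between Nb and naive (17 higher in Nb, 16 lower), 648 between LPS and naive (327 higher in LPS, 321 lower) and 389 between Nb and LPS (116 higher in Nb, 273 lower). Of these probes, 5670 lie in regions named only by their coordinates, of which 11, 310 and 184 were called. One on chromosome 6, from 145936225 to 145965575 in build mm9, was higher in LPS than in naive by 4.52 ± 0.34 on the log2 scale (n = 3 against 2, adjusted p = 0.00172). No group has 4 or more arrays, so no array was tested for lying far from its group.

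Of 27 type 2 genes 6 were higher in Nb than in naive, which the infection itself may explain and which cells of other types in the sort could also explain. A larger share of macrophages and dendritic cells was predicted to raise their markers by a median of 1 or more on the log2 scale. The median of 23 was 0.0446 (95% bootstrap interval over markers -0.34 to 0.49), so the markers as a set did not rise by that much. C1qa had a level of 1.75 ± 0.86 (SD, n = 2) in naive and 1.65 ± 0.81 (n = 3) in Nb, and Csf1r 6.34 ± 0.68 and 6.93 ± 0.19. Single markers parted. Car4 rose by 2.10 (adjusted p = 0.0356, lost without any one array) and Ctsk had levels of 2.42 ± 0.61 and 4.37 ± 0.37. Itgax was lower, but not called (-1.03, adjusted p = 0.0754). Siglecf, shared with eosinophils, was not called (0.90), while another of its probes gave 1.62 (unadjusted p = 0.00207). The interval does not measure the spread between arrays, of which naive has 2. A small gain in share would also raise the markers by less than the predicted 1. A larger share is therefore not excluded. For eosinophils the median of 5 markers was -0.0443 (-1.03 to 0.34), with Ccr3 at 0.75 ± 0.13 and 0.70 ± 0.50, and the same limit holds. Basophils or mast cells stay open, since the median of 5 markers was 1.48 (0.55 without Nb 2) but its interval ran from -1.24 to 1.98. Of these markers 0 were called. Gata2, whose change is that median, had levels of -0.90 ± 0.50 and 0.58 ± 0.12, and Kit 0.36 ± 0.69 and 2.34 ± 0.50. Fcer1a went the other way, with levels of -1.95 ± 0.07 and -3.19 ± 1.19. RNA of lung epithelial cells stays open too, since the median of 15 markers was 1.34 (0.22 to 2.77) and Sftpc had levels of 4.50 ± 1.10 and 7.27 ± 0.59, although the sort was meant to keep neutrophils alone, and a change of expression within an unchanged share of macrophages was not tested.

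Rag1, Dntt, Ly6d and Myb were higher in naive than in Nb; these 4 were picked after their values were seen, and no list of precursor genes had been fixed. B lineage cells in the naive sort would have brought other B cell markers, and the median of 10, Nb minus naive, was -1.37 (95% bootstrap interval -1.80 to -0.93), with Cd79b at 3.15 ± 0.36 (SD, n = 2) in naive and 1.32 ± 0.31 (n = 3) in Nb and Ms4a1 at 2.99 ± 0.0047 and 1.25 ± 0.40. T cells would have brought theirs, and the median of 16 was -1.12 (-1.24 to -1.01), with Cd3g at 2.70 ± 0.44 and 1.56 ± 0.12. A larger share of lymphoid cells left in the naive sort is therefore a candidate explanation that remains a hypothesis, and a biological difference between naive and infected neutrophils was not tested apart from it. Rag1 (-5.24) and Dntt (-3.73) fell further than both marker medians. In Nb, Rag1 was above background on 1 of 3 arrays and Dntt on 2. The medians are over B and T cell markers, which need not follow the share of precursor cells, so this gap decides nothing. Of 2 further precursor genes, Vpreb3 fell by 2.11 in Nb (adjusted p = 0.0249) and by 1.61 in LPS (0.0222), while Vpreb1, at the floor of -4.16 on both naive arrays, was not called in Nb (1.05, 0.156) and was higher in LPS (2.90, 0.00411), which excludes nothing.

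Naive and LPS share no slide, so a difference between slides may add to the genes called between them. Among 1454 of these genes the change from slide 1 to slide 2 within Nb had a median share of 0.0717 of the LPS minus naive change (95% bootstrap interval over genes 0.0596 to 0.0863). A share under 0.5 had been set as evidence against a slide effect, but that bound was too generous: slide 2 holds a single Nb array, and the interval over genes does not measure how far that array strays by itself. With slide as a block 8 genes were called and 1460 of 1460 kept their direction; Nos2 went from 4.74 to 4.84 (adjusted p = 0.0628), and list medians were 1.11 for interferon-stimulated genes (9.16e-05), 0.89 for TLR4 and NF-kappaB genes (4.99e-07) and, down from 0.62, 0.15 for cell cycle genes (0.574), but this fit ties the slides through the same Nb array, so a part played by the slide stays open.

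Between Nb and LPS limma called 1191 genes, and the highest count among the 9 other splits of the 6 arrays into 3 and 3 was 0, with 303 to 830 genes at an unadjusted p under 0.05. The real split is 1 of 10, and 10 splits are too few for a share under 0.05. Each other split mixes Nb with LPS arrays, so any real difference between them widens its spread and lowers its count. The counts of 0 therefore decide nothing.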

How the results depend on the processing

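The floor at 1, the percentile of detected probes and the test of all probes were chosen after seeing the data; the other settings were planned. Main counts were 265 genes for Nb against naive, 1460 for LPS against naive and 1191 for Nb against LPS. They stayed within 1.5 times of these with quantile normalization (302, 1667, 1352), probes above background on all arrays (316, 1519, 1347), the mean of a gene's probes (227, 1413, 1129) and the percentile of detected probes (354, 1721, 1395). The cause was not tested for any shift below, except that fewer arrays or more coefficients leave fewer degrees of freedom. With slide as a block 17, 8 and 193 genes were called. Of the main calls, 265 of 265, 1460 of 1460 and 1191 of 1191 kept their direction. In every called gene the arrays of the 2 groups did not overlap. For Nb against naive and Nb against LPS, a called gene with a value on every array thus could not change direction. Within slide 1 limma called 0 genes for Nb against naive (2274 at an unadjusted p under 0.05), and within slide 2 it called 0 for Nb against LPS (2089). A random slide block gave 2895 for LPS against naive (consensus correlation -0.10). The authors' values gave 675, 2379 and 2056, and the trended robust prior 618, 2208 and 1806. The replicate block gave 38, 303 and 683, although replicate numbers do not pair the samples (same-number r from -0.0825 to 0.101). The 2 groups alone gave 25 for Nb against naive and 502 for LPS against naive. For Nb against naive, normexp background gave 553, median signal with quantile normalization 456, array weights 427, the floor at 1 159, all probes 146 and no filter 167 (773 for Nb against LPS). The share of genes higher in Nb than in naive was 64.5%, against 43.1% with no filter (72 higher, 95 lower), 52.6% with the trended robust prior and 82.4% with slide as a block.

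Leaving out 1 array gave 17 (without Nb 3) to 197 (without LPS 2) genes for Nb against naive, 265 (without naive 1) to 1263 (without Nb 3) for LPS against naive and 442 (without Nb 1) to 1093 (without LPS 2) for Nb against LPS. A group left with 1 array is assumed to vary like the others. Of 211 calls of named genes, 108 to 165 held without 1 array, 38 with slide as a block, 127 with no filter, 118 with 2 groups alone and 108 of 210 with the replicate block. Calls held more often with normexp (210), the random slide block (211), quantile normalization (205) and the authors' values (200 of 203). The random slide block had a negative consensus correlation (-0.10), so its 211 are no check of a slide difference. Tgm2, Nb against naive, with a single naive value, reversed to -0.32 with probes above background on all arrays, where another probe stands for it.

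Of the list calls (13, 9 and 9), an estimated correlation kept 0, 0 and 0. Of all 31, fry kept 22, slide as a block 25 (4 lists called for LPS against naive) and the replicate block 29. Quantile normalization kept 28, normexp 31, the authors' values 27 and leaving out 1 array 27 to 31. Slide 1 alone kept 13 of 13 for Nb against naive, on the same arrays that the slide block compares there. For Nb against LPS, slide 2 alone and the slide block rest on the same single Nb array. Neither tells how these lists vary between Nb arrays. The shared response (77 genes higher and 59 lower in both) had 276 genes with normexp and 3 with slide as a block. Not run were a random slide block for lists, since camera takes no block, and LPS against naive or the shared response within a slide, which has none of both groups. Normexp used median signal, since the files hold no mean signal. Between 43.5% and 50.5% of spots were well above background, which limits what dim genes can show.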

Other observations

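The groups of genes here were fixed beforehand, and the choice to describe them together was made after their values were seen; values come from limma or camera, on all arrays unless one is named as left out. Enzymes and receptors of lipid mediators parted between Nb and LPS, with 4 of 21 eicosanoid genes higher in Nb and 2 lower. Higher were Cysltr1, a leukotriene receptor (1.63), Hpgd, which breaks down prostaglandins (1.40), Ltb4r1, the receptor for leukotriene B4 (1.35), and Alox5ap (1.17). Lower were Ptger2, a prostaglandin E2 receptor (-1.69), and Ptgs2, the inducible cyclooxygenase (-1.30). The Cysltr1 call ended without any one array of the 2 groups except LPS 2 (highest adjusted p = 0.0821), the Hpgd call without Nb 1, Nb 3, LPS 1 or LPS 3 (0.0742), the Ltb4r1 call without any one Nb array or LPS 3 (0.0748) and the Ptger2 call without LPS 3 (0.0555). In the slide block fit the adjusted p of these 4 was 0.183, 0.0534, 0.130 and 0.0785, and that of Alox5ap and Ptgs2 0.0915 and 0.0601; the Alox5ap call ended without any one Nb array (highest 0.0574). As a list they were not called (median 0.28, adjusted p = 0.136).

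Among 24 apoptosis and survival genes 4 were higher in LPS than in naive, groups that share no slide (Cflar at 1.89, Bax at 1.47, Bak1 at 1.38 and Casp8 at 1.10; list median 0.23, adjusted p = 0.176). In the slide block fit their adjusted p was 0.165, 0.173, 0.272 and 0.508. The Bax call ended without naive 1, naive 2 or LPS 3 (highest 0.104), the Bak1 call without naive 1 or naive 2 (0.122) and the Casp8 call without any one array (0.215). Hmox1, the haem oxygenase, was higher than naive by 2.54 in Nb and by 2.18 in LPS. Its slide block values were 2.33 (adjusted p = 0.0745) and 1.57 (0.384). Its call in Nb ended without any one naive or Nb array (highest 0.128), and its call in LPS without naive 1, naive 2 or LPS 3 (highest 0.0870). In Nb against naive, basophil and mast cell markers had 0 of 5 called (median 1.48, adjusted p = 0.124; 0.55 without Nb 2) and eosinophil markers 0 of 8 (median -0.37, adjusted p = 0.444).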
